A study of Homo sapiens with 7 samples.

How the data were processed

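RNA abundance was measured by bulk RNA sequencing in 7 libraries labelled as RPMI 8226, a human line of multiple myeloma, which is a cancer of antibody-secreting plasma cells. Per the labels, 2 libraries came from wild-type cells (WT), 2 from cells in which HDAC6 was knocked out (KO) and 3 from cells carrying a 2-residue change in the ubiquitin-binding zinc finger of HDAC6 (RY), and both edited lines were made with CRISPR-Cas9. The label protocols give a total RNA kit and a stranded TruSeq library. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

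The count table is the authors' deposited raw read count per Ensembl gene, without normalization. The submitters' processing notes name FastQC, STAR 2.7.4, HTSeq 0.9.1, edgeR 1.34.1 and the GRCh38 build, without stating roles or order. The annotation release, the strand setting and the filters on reads were not given in the sources used here, so overlapping and antisense genes, and near-identical copies such as the immunoglobulin constant genes and the HSPA1A and HSPA1B pair, are uncertain. A normalized table deposited by the authors holds a score per gene that equals the raw count divided by 1 factor per library, to within 0.1% for 100% of values, for 21394 genes. Its columns sum to between 920621 and 1071600, so it is scaled by a composition factor besides depth. The authors' deposited tables of KO against WT and RY against WT give a log2 fold change, an average log2 CPM, an F score, a p-value and an adjusted p-value per gene, and list only genes with an absolute log2 fold change of at least 1 and an adjusted p-value under 0.05. Only the raw counts entered the tests described here.

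The count table held 60666 gene identifiers, of which 60437 were paired with a symbol by the gene name table and 58420 with a position in GENCODE release 29 on GRCh38. Library totals ran from 31368968 to 42813888 counted reads. A level of 3 reads, used as the floor for a gene with no reads, came to 0.0393 CPM over the WT libraries together, 0.0435 over KO and 0.0262 over RY. Floors and intervals cover counting error only, at a level of 95%. Replicates were compared before averaging: a chi-square per gene over genes with at least 20 reads was 78.6 between the WT libraries, 28 between the KO libraries and 7.92 to 16.5 between pairs of RY libraries, so no library repeated another within sampling noise. Between WT and KO it ran from 64.08 to 108.9. The lowest, for WT replicate 1 and KO replicate 2, lay below that between the WT libraries, while their log2 CPM correlated less (0.958 against 0.986).

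Differential expression was tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, on all 7 libraries in a single fit with a term per group and no covariates, so that the groups share an estimate of the spread. By the chi-square above, the libraries labelled RY lay closer together than those of WT or KO. The shared estimate may therefore be too small for KO against WT. Library sizes were scaled by TMM, with factors from 0.932 to 1.09, and edgeR's filterByExpr with a minimum count of 10 left 18281 genes. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 and a fold of at least 2. Every adjusted p for a gene comes from this test unless another is named. CPM values are edgeR counts scaled to the TMM-adjusted library size, given as mean ± SD. Folds are ratios of the reads of a group over its TMM-scaled library sizes, so they can differ slightly from the ratio of the means. Where every library of the lower group had 0 reads the fold was computed against the floor and is written as a lower bound, and with 1 to 3 reads it is given with its counting interval. Levels of Y-linked genes and of XIST are not reported.

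Before the data were examined, 38 gene lists were fixed, covering pathways, complexes and markers of cell types. Each was tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the 38 lists. No camera call in any comparison held with a correlation estimated for each list, and the adjusted p of that version is given beside each call. Fry was run as an alternative. It tests whether the genes of a list move on balance in a shared direction and does not set them against other genes. The genes to be named were fixed by a rule at the same time: HDAC6; the 6 largest increases and 6 largest decreases of KO and of RY against WT, and 4 of each for RY against KO, among called genes with a mean of at least 5 CPM in the higher group, no overlap between libraries and a symbol that is not clone-based; up to 3 called members of each list by adjusted p, or its most abundant members where fewer than 2 were called; and 4 genes in each direction among those called in both comparisons with WT. Genes named outside this rule are said to be so.

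The test was checked on simulated counts with the means and depths of these libraries. Genes changed 2-fold were recovered at the adjusted p threshold for 73% of 100 in KO against WT, 72% in RY against WT and 60% in RY against KO. With the 2-fold minimum added, as for the calls here, 38%, 38% and 41% were recovered. Genes changed 4-fold were recovered for 97%, 96% and 99% by either rule. Of the genes simulated without a change, 7, 2 and 4 were called with the 2-fold minimum, in runs of 17528, 17516 and 17534 genes in all. Each run changed 100 genes at each fold, far fewer than the 9007 genes called in RY against WT.

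Alternatives planned beforehand were relative log expression size factors, library size only, leaving out immunoglobulin genes, no filter on low counts, a mean of at least 1 CPM in a group, the older quasi-likelihood method of edgeR, DESeq2 1.42.0, limma-voom, the adjusted p alone, a test against 1.5-fold, fits of only the 2 groups compared, a replicate block, and leaving out each library in turn. After the data were seen, fits without genes that RNA of the RY kind could supply to the WT libraries, without genes on the X chromosome and with crossed replicate numbers were added. Neighbouring genes were taken from GENCODE positions. Along the X chromosome, protein-coding genes with a mean of at least 5 CPM in WT were used, HDAC6 excepted. Figures were drawn with matplotlib 3.10.9.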

Results

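Transcript levels were counted in 7 libraries that the labels assign to the myeloma line RPMI 8226, 2 labelled WT, 2 labelled KO for an HDAC6 knockout and 3 labelled RY for a 2-residue change that removes ubiquitin binding by the zinc finger of HDAC6. HDAC6 is a mostly cytoplasmic deacetylase that acts on tubulin and also binds free ubiquitin chain ends. The comparisons set each edited line against WT, to ask how gene expression differs with the knockout or with the 2-residue change. The labels do not say whether replicates are separate clones. Differences between lines therefore cannot be told apart from effects of the edits. The WT libraries held 38662718 and 42813888 counted reads, the KO libraries 36670541 and 34768942, and the libraries labelled RY 37530082, 38112341 and 31368968. Across genes, log2 CPM correlated at 0.986 between the WT libraries, 0.991 between the KO libraries and 0.994 to 0.995 among the libraries labelled RY. The correlation was 0.946 to 0.958 between WT and KO, and 0.682 to 0.753 between the libraries labelled RY and the other 4. Genes are not independent replicates in these correlations.

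The targeted gene was lower in KO and not lower in the libraries labelled RY. HDAC6 (ENSG00000094631, X chromosome, 48801377 to 48824982, GRCh38) stood at 67.2 ± 14.2 CPM in WT (SD, n = 2), 15.9 ± 4.38 CPM in KO (n = 2) and 99.1 ± 10.2 CPM in RY (n = 3). KO held 23.7% of the WT level, a log2 fold change of -2.08 (SE 0.21, adjusted p = 0.000189 by edgeR). The libraries labelled RY were 1.47-fold above WT (log2 0.56, SE 0.18, adjusted p = 0.0197), under the 2-fold minimum, and that adjusted p became 0.082 without WT replicate 1, 0.0851 without RY replicate 2 and 0.0642 with a replicate block (0.00157 to 0.0851 over the alternatives planned for HDAC6). RY exceeded KO 6.20-fold (adjusted p = 2.89e-06). RNA levels do not show whether the remaining KO transcripts encode protein, and gene counts do not show the RY edit.

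**Figure D1:**
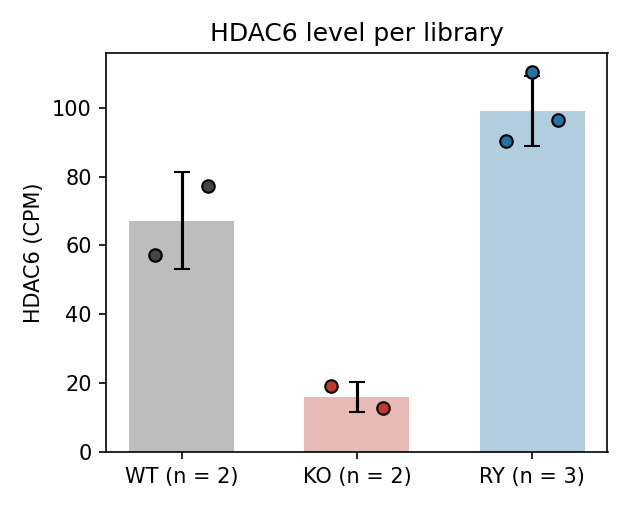
HDAC6 level in CPM on the y axis for the WT, KO and RY libraries. Points are libraries, bars are group means from 0 and error bars are SD; WT averages 67.2, KO 15.9 and RY 99.1 CPM.

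Interferon-stimulated genes, which cells induce against viruses, were the group most clearly lower in KO than in WT. Of 46 measured, 31 fell and 0 rose, with a median log2 fold change of -1.62. IFI6, an interferon-induced mitochondrial protein, fell from 261 ± 4.30 to 35.6 ± 1.19 CPM (7.34-fold, adjusted p = 1.03e-05). TRIM22, an antiviral ubiquitin ligase, fell from 41.6 ± 1.93 to 2.26 ± 0.779 CPM (18.2-fold, adjusted p = 3.99e-06), and IFI44 from 39.7 ± 6.40 to 3.86 ± 0.732 CPM (adjusted p = 8.12e-06). B cell genes moved the same way, with 11 of 28 lower and 0 higher. MS4A1, which encodes the B cell surface antigen CD20, fell from 13.6 ± 3.22 to 0.608 ± 0.0541 CPM (22.5-fold), FCRLA from 20.8 ± 6.76 to 2.42 ± 0.279 CPM and the kinase gene LYN from 16.8 ± 0.634 to 4.78 ± 0.158 CPM.

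In all, 1991 of 18281 genes changed between KO and WT, 673 higher and 1318 lower in KO. The largest decreases included CDH4, a cadherin, from 96.9 ± 6.18 CPM to 0.015 CPM (6693-fold, counting interval 1201 to 264400), and MME, the surface peptidase CD10, from 22.1 ± 2.48 to 0.0141 CPM (1529-fold, interval 274 to 60440). KALRN and the transcription factor gene SALL1 had 0 reads in KO and were at least 426-fold and at least 293-fold lower than in WT. KRT9 fell from 30.1 ± 4.34 to 0.030 CPM and LILRB1 from 11.1 ± 3.18 to 0.015 CPM. With so few KO reads, these log2 fold changes moved with the KO library left out: without KO replicate 1 they were -11.5 for CDH4, -12.7 for MME, -8.89 for KRT9 and -8.38 for LILRB1, and without KO replicate 2 -14.9, -9.43, -13.2 and -11.7. The largest increases were ALDH1A1, a retinaldehyde dehydrogenase, at 10.7 ± 2.65 CPM against 0.0387 in WT (274-fold, interval 93.5 to 1333), the homeobox gene MEOX2 at 37.0 ± 0.165 against 0.249 CPM, and FARP1 at 159 ± 14.6 against 1.58 CPM. RPH3A rose from 0.381 ± 0.0112 to 18.7 ± 0.349 CPM, and the activin receptor gene ACVR1C and the stem cell receptor gene LGR4 rose 43.4-fold and 42.6-fold (LGR4 log2 5.40, or 6.04 without WT replicate 2). The plasma cell program itself showed 2 members higher and 2 lower of 27: JCHAIN, the joining chain of secreted antibody, fell from 5196 ± 409 to 2156 ± 118 CPM (adjusted p = 0.00407, and 0.367 with DESeq2, in a range of 0.000247 to 0.367 over the alternatives planned for named genes), while GPRC5D, a myeloma surface antigen, rose from 6.09 ± 0.563 to 18.4 ± 2.02 CPM.

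Of the other groups, 7 of 36 adhesion and matrix genes fell and 1 rose, among them fibronectin, FN1, from 3744 ± 149 to 654 ± 326 CPM (log2 -2.52, or -3.12 without KO replicate 2, adjusted p = 0.000616) and the neural adhesion molecule NCAM1 from 271 ± 4.12 to 46.7 ± 7.68 CPM. Among cytoskeletal genes 4 of 36 fell and 1 rose. Thymosin beta 4, TMSB4X, which binds actin monomers, fell 6.09-fold to 123 ± 21.9 CPM, and PLS3, an actin bundling protein, rose 5.30-fold to 194 ± 27.7 CPM. TMSB4X starts at 12975108 on the X chromosome, within the stretch up to HDAC6 that was lower in KO as a block, described below. Its log2 fold change of -2.6 lay below the median of that stretch, -0.97. Chemokine and cytokine genes went both ways, with 8 of 34 higher, such as LTB (log2 2.55, or 3.15 without WT replicate 2), and 6 lower, such as BMP6 (4.02-fold) and CXCL8 (14.7-fold). Of 29 HDAC6 partners and substrates 1 rose and 1 fell: CTTN, an actin-binding substrate, rose 3.75-fold (adjusted p = 0.000234), and the inflammasome gene NLRP3 fell 7.23-fold from 0.837 ± 0.0458 CPM (adjusted p = 0.00319). Housekeeping groups moved little: the median log2 fold change was -0.11 over 31 proteasome subunits, 0.074 over 70 cytosolic ribosomal proteins and 0.12 over 47 nuclear oxidative phosphorylation genes. It was -0.21 over 29 unfolded protein response genes and 0.11 over 17 HDAC and sirtuin genes apart from HDAC6. Camera called none of the lists named here, with adjusted p from 0.153 for the cytoskeleton to 0.87 for the proteasome.

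**Figure D2:**
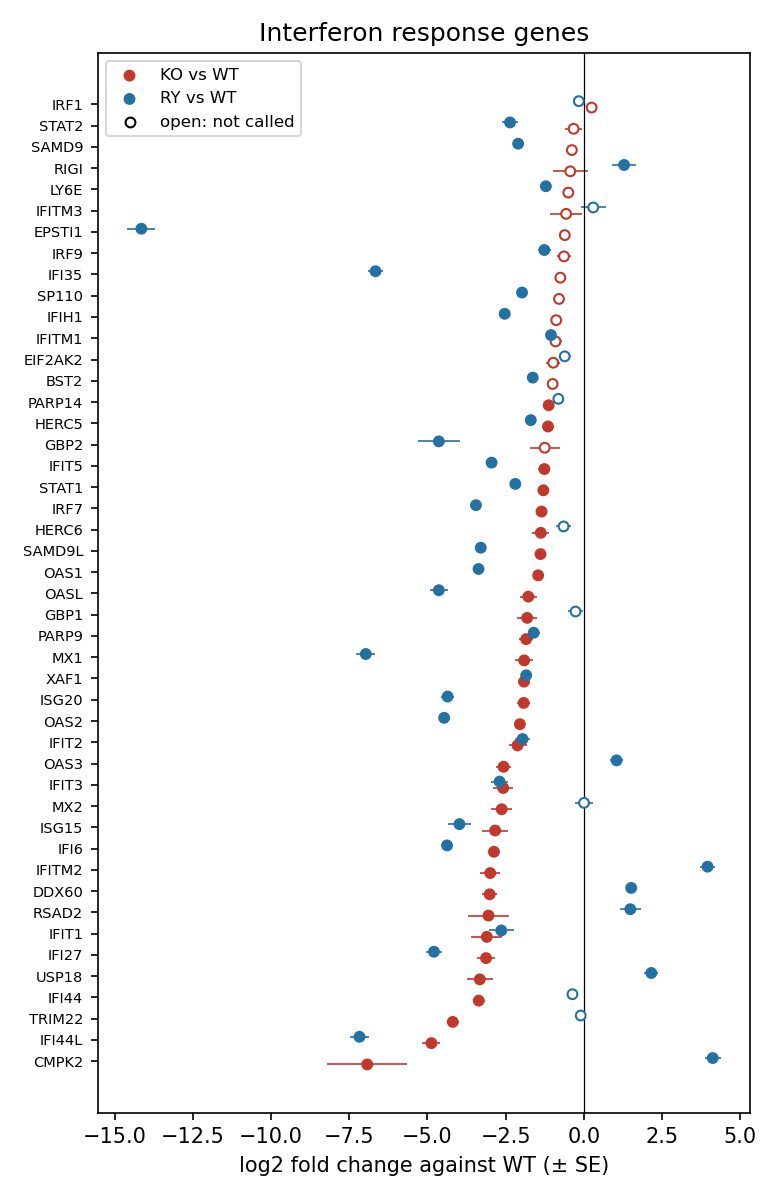
Log2 fold change against WT on the x axis (± SE) for each measured interferon response gene, for KO and for RY; filled points passed the test and open points did not. Fitted values of genes with no reads in RY depend on the prior count; 31 genes are lower in KO and 30 lower in RY.

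By camera, 4 of the 38 lists were lower in KO: interferon response (adjusted p = 2.05e-31, and adjusted p = 0.252 with an estimated correlation), B cell identity (2.46e-10, and adjusted p = 0.331 with an estimated correlation), genes beside HDAC6 on the X chromosome (1.9e-07, and adjusted p = 0.252 with an estimated correlation) and myeloid cell markers (0.0141, and adjusted p = 0.887 with an estimated correlation). Adjusted over the list alone, 32 interferon genes, 11 B cell genes, 3 genes beside HDAC6 and 5 myeloid markers were lower and 0 higher. The median of the B cell list was -0.98, or -0.89 with genes without reads at their bound. The number of lists called was 14 without WT replicate 1, 14 without WT replicate 2 and 7 without KO replicate 1. Every KO library lay below every WT library for 42 of the 46 interferon genes, where chance gives 16.7% for a single gene. Genes regulated together are not independent, so these are not 46 separate tests. Of the 46, 33 were higher in WT replicate 1 than in WT replicate 2.

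Genes beside HDAC6 were lower in KO as a block. All 20 measured neighbours on the list had a negative log2 fold change, with a median of -0.60, and 3 passed the test with a 2-fold minimum: EBP, a sterol isomerase, fell from 82.8 ± 11.2 to 39.3 ± 5.38 CPM, WDR13 from 45.7 ± 7.24 to 22.5 ± 3.32 CPM and PRAF2 from 1.31 ± 0.714 to 0.289 ± 0.0688 CPM. Each of these calls depended on single libraries. WDR13 also fell short of the 2-fold minimum with library size only (log2 fold change -0.977), and PRAF2 lost the adjusted p threshold with a replicate block (0.0564 by edgeR). EBP had a log2 fold change of -0.94 without WT replicate 1 and -0.94 without KO replicate 1, and WDR13 -0.85 without WT replicate 2 and -0.85 without KO replicate 2. PRAF2 had an adjusted p of 0.0708 without WT replicate 2, 0.0791 without KO replicate 1 and 0.0975 without KO replicate 2, in a range of 9.75e-05 to 0.0975. From the short-arm end to HDAC6, 102 of 103 protein-coding genes had a negative log2 fold change, with a median of -0.97 (quartiles -1.21 and -0.77), or 51% of the WT level, and 90 had an adjusted p under the threshold. The next 13 genes, starting at 48893447 to 49235467, had a median of -0.40, and the 204 genes from 49687450 on a median of -0.0049. This second boundary was chosen after the values were seen. The medians of the short-arm stretch and of the stretch from 49687450 on differed by -0.97 (two-sided permutation test over genes, 100000 resamples, p = 1e-05, the smallest they can give). Genes are not independent replicates in this test.

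**Figure D3:**
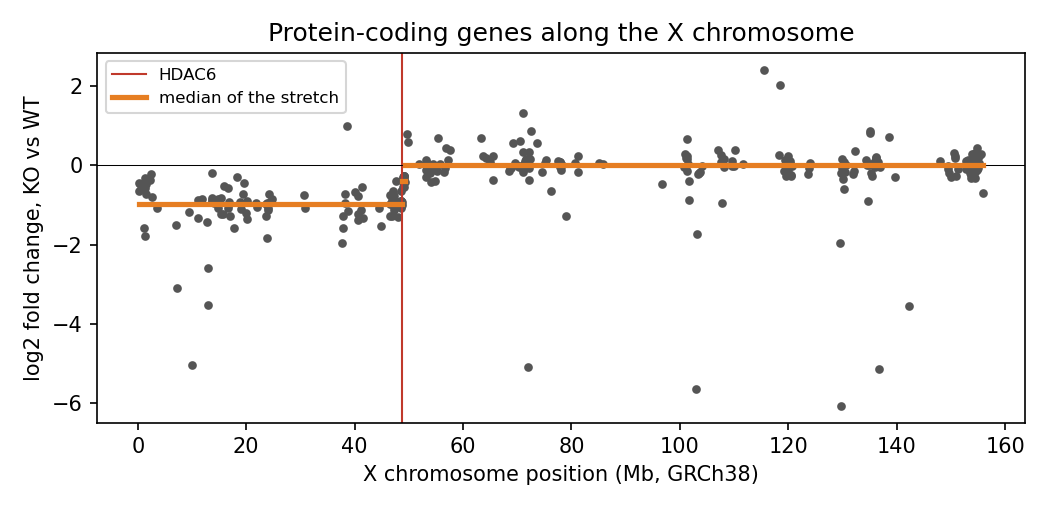
Log2 fold change of KO against WT on the y axis for protein-coding genes by position on the X chromosome (Mb, x axis), with HDAC6 marked by a vertical line. Orange lines are the medians of 3 stretches, -0.97 from the short-arm end to HDAC6, -0.40 over the next 13 genes and -0.0049 beyond.

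Of 11 measured myeloid markers 3 were lower in KO than in WT, and these 3 had a high level in the libraries labelled RY. MPO, the peroxidase of granulocyte precursors, stood at 58.9 ± 24.6 CPM in WT, 0.0844 and 3.51 CPM in the KO replicates and 980.1 ± 67.1 in RY. Its log2 fold change between KO and WT was -5.06, with -4.07 without KO replicate 1 and -9.36 without KO replicate 2. AIF1 stood at 7.50 ± 2.40, 0.435 ± 0.0210 and 161 ± 8.64 CPM, and the integrin gene ITGAM at 3.08 ± 0.278, 0.219 ± 0.0717 and 39.8 ± 0.865 CPM. Over 210 genes with at least 20 CPM in RY and under 1% of that in KO, the median WT level was 4.04% of the RY level in replicate 1 and 7.09% in replicate 2. A WT share of 5.56% of the RY level would account for at least 50% of the WT level of 450 of the 1318 genes lower in KO, including all 3 myeloid markers called, 2 of the 31 interferon genes, 2 of the 11 B cell genes, 3 of the 7 adhesion and matrix genes, 1 of the 4 cytoskeletal genes and 1 of the 6 chemokine and cytokine genes. It would also account for 88.8% of the WT level of NLRP3 and, short of that limit, for 41.6% of LYN and 49.1% of CD22, a further B cell gene lower in KO that was named after its values were seen. Without such genes, an alternative chosen after seeing the data, 29 of 44 interferon genes, 9 of 23 B cell genes and 4 of 29 adhesion and matrix genes remained lower (median log2 fold change of the last -0.0561 in place of -0.186), no myeloid marker list could be tested, and 1454 genes were called.

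**Figure D4:**
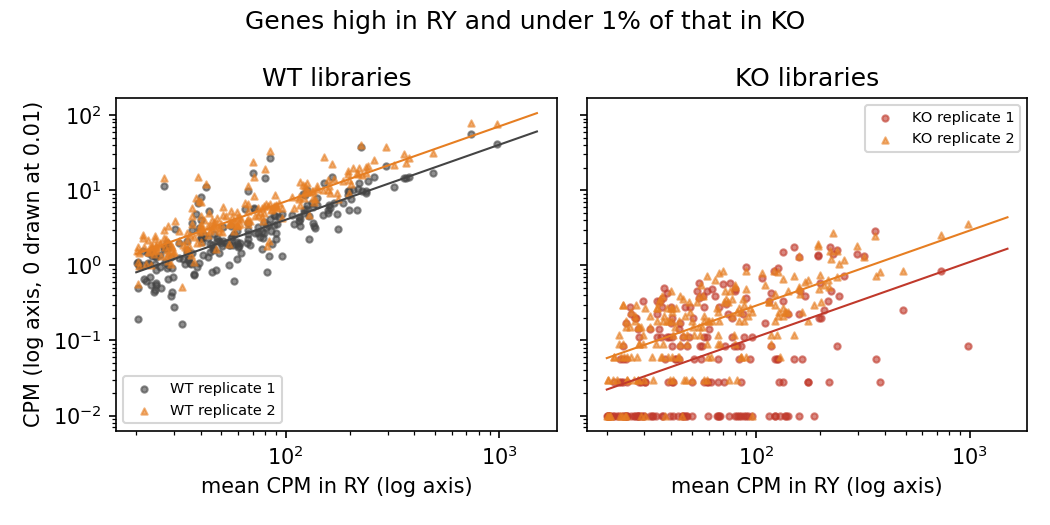
CPM in each WT (left) and KO (right) library on the y axis against mean CPM in RY on the x axis, both log axes, for 210 genes with at least 20 CPM in RY and under 1% of that in KO. Lines are the median share of the RY level, 4.04% and 7.09% in WT and 0.111% and 0.291% in KO, where the choice of genes makes it low.

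Antibody genes and most plasma cell genes were lower in the libraries labelled RY than in WT. Of 27 plasma cell identity genes, 21 fell and 3 rose, with a median log2 fold change of -4.76. SDC1, which encodes the myeloma surface proteoglycan CD138, went from 201 ± 61.7 CPM in WT to 0.0327 ± 0.0283 in RY (5703-fold, adjusted p = 9e-11), and MZB1, a chaperone of antibody assembly, from 1346 ± 58.9 to 2.91 ± 0.549 CPM. Of 12 immunoglobulin constant genes 11 fell and 1 rose; IGLC3 went from 2278 ± 286 to 0.120 ± 0.0939 CPM (log2 -14.2, or -14.8 without RY replicate 3), and IGKC from 225 ± 27.1 to 0.0696 ± 0.0271 CPM. Immunoglobulin genes made up 1.59% and 1.93% of reads in WT, 2.05% and 1.83% in KO and at most 0.00059% in RY.

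Against WT, 9007 of 18281 genes changed in RY, 4363 higher and 4644 lower. Ranked by fitted log2 fold change, the largest decreases were genes with 0 reads in all 3 libraries labelled RY. Among them were the T cell coreceptor gene CD8B, 428 ± 10.5 CPM in WT (at least 16370-fold lower), and the desmosomal cadherin gene DSG2 (at least 9139-fold). The others were the transcription factor gene TEAD1 (at least 5403-fold), IGHG4 (at least 5157-fold), the peptidase gene BLMH (at least 4364-fold) and the glutamate receptor gene GRIA4 (at least 4212-fold). Fitted values of genes without reads depend on the prior count. The bounds do not place these genes above a fall measured with reads, such as that of IGLC3. The largest increases were CTNNA2, NOG, MUC19, NEGR1, INHBA and RAG2. INHBA, an activin subunit, rose from 1.31 ± 0.714 to 81.4 ± 3.00 CPM (60.9-fold), and RAG2, part of the recombinase of antigen receptor genes, from 0.383 ± 0.267 to 20.3 ± 0.745 CPM. Without WT replicate 2 the log2 fold changes were 7.40 for CTNNA2, 11.2 for NOG, 7.58 for MUC19, 7.38 for NEGR1, 6.65 for INHBA and 6.67 for RAG2, against 6.57, 6.57, 6.52, 5.97, 5.93 and 5.68 with all libraries; without WT replicate 1 they were 5.67 for NOG and 5.31 for NEGR1. Counting genes with at least 10 CPM in a group and under 0.1 CPM in the other, 421 genes of WT were off in RY and 0 genes of RY were off in WT. RNA of the RY kind in WT, at the share given above, would hold down this second count and the folds of increase. Against KO, 170 genes of RY were off.

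Some unfolded protein response and class I presentation genes were lower in RY, and most members of either list were not called. Of 29 unfolded protein response genes 12 fell and 0 rose, among them HSPA5, the main chaperone of the endoplasmic reticulum, from 1582 ± 188 to 328 ± 15.3 CPM (4.82-fold) and HYOU1 from 853 ± 14.4 to 296 ± 1.87 CPM. Of 20 class I presentation genes 9 fell and 0 rose, with the peptidase gene ERAP2 falling from 129 ± 3.70 to 18.3 ± 0.992 CPM. Interferon genes went mostly down, with 30 of 46 lower and 7 higher; OAS2 fell 22.1-fold from 374 ± 69.8 CPM and IFI35 fell from 68.4 ± 20.2 to 0.671 ± 0.0733 CPM. Of 34 chemokine and cytokine genes 18 fell and 8 rose; CXCL12 went from 132 ± 5.61 to 0.0181 ± 0.0160 CPM, and the chemokine receptor gene CCR1 fell 60-fold. Most genes usually silent outside germ cells and most epithelial markers were lower too: 10 of 12 cancer-testis antigens fell and 2 rose, with MAGEA1 at least 2133-fold lower, and 9 of 11 epithelial markers fell and 1 rose, with EPCAM falling from 82.0 ± 15.3 to 0.0101 ± 0.0175 CPM (log2 -12.7, or -14.6 without RY replicate 3).

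Most of the measured myeloid markers were higher in RY. Some cell cycle genes were too, at no larger a share than over all genes, where 4363 of 18281 rose and 4644 fell. Of 11 myeloid markers 8 rose and 1 fell, with AIF1 21.2-fold and ITGAM 12.9-fold above WT. Of 43 genes of the G1/S transition 10 rose and 0 fell, such as CCNE2, a cyclin of S phase entry, from 11.8 ± 2.03 to 44.2 ± 1.79 CPM; 17 rose without WT replicate 1 and 6 without WT replicate 2. Of 52 G2/M genes 10 rose and 3 fell, and camera did not call that list (adjusted p = 0.0699). Of 17 HDAC and sirtuin genes apart from HDAC6, 1 rose, 1 fell and 15 were not called. This was a smaller share than over all genes, where 9007 of 18281 changed. The deacetylase gene HDAC2 rose 3.51-fold to 384 ± 27.5 CPM and SIRT5 fell 3.79-fold. Of 29 HDAC6 partners and substrates 9 fell and 4 rose, also a smaller share than over all genes. The peroxiredoxin gene PRDX1 went from 610 ± 147 to 0.332 ± 0.0431 CPM (1822-fold, adjusted p = 1.42e-09), and SQSTM1, the autophagy receptor p62, fell 7.24-fold to 56.1 ± 0.766 CPM. MYC fell from 982 ± 160 to 323 ± 34.5 CPM (3.08-fold). CDKN2C, an inhibitor of CDK4 and CDK6, rose from 5.18 ± 2.58 to 136 ± 2.92 CPM (log2 4.70, or 5.33 without WT replicate 2).

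**Figure D5:**
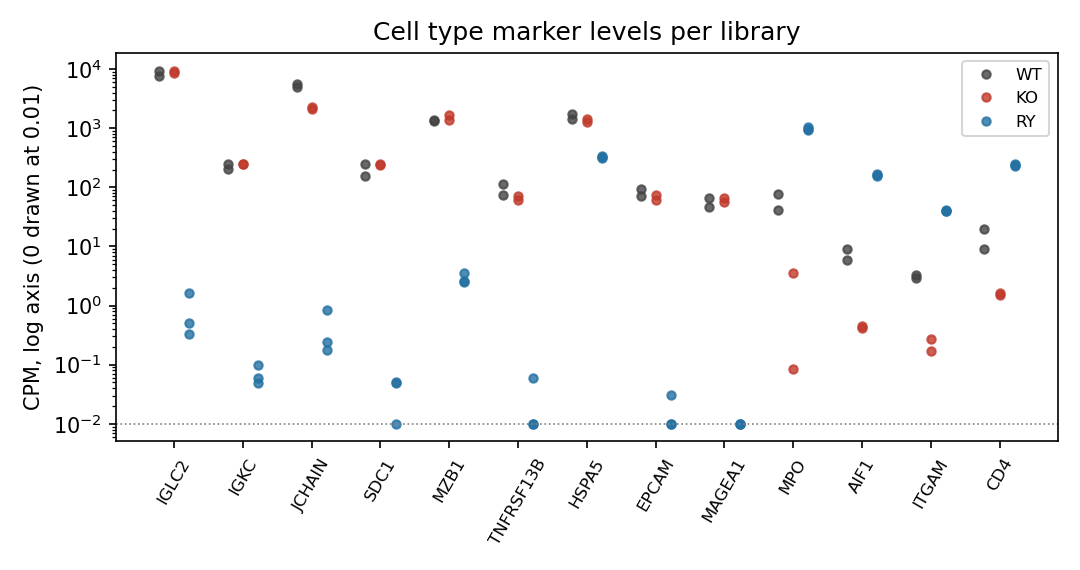
CPM per library on a log y axis for marker genes on the x axis, with WT, KO and RY libraries in different colours and 0 drawn at 0.01. SDC1, EPCAM and MAGEA1 lie at or near 0 in RY, while MPO averages 980.1 CPM in RY, 58.9 in WT and 1.80 in KO.

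Camera called 10 of the 38 lists, 8 lower and 2 higher in RY. The lower ones were plasma cell identity (adjusted p = 6.24e-14, and adjusted p = 0.418 with an estimated correlation), immunoglobulin constant genes (7.82e-14, and adjusted p = 0.26 with an estimated correlation), interferon response (4.49e-06, and adjusted p = 0.549 with an estimated correlation), epithelial markers (4.15e-05, and adjusted p = 0.549 with an estimated correlation), cancer-testis antigens (0.00383, and adjusted p = 0.408 with an estimated correlation), class I presentation (0.0221, and adjusted p = 0.418 with an estimated correlation), chemokines (0.0257, and adjusted p = 0.549 with an estimated correlation) and unfolded protein response (0.0395, and adjusted p = 0.701 with an estimated correlation). The higher ones were myeloid markers (0.0257, and adjusted p = 0.549 with an estimated correlation) and G1/S genes (0.0395, and adjusted p = 0.954 with an estimated correlation). Adjusted over the list alone, the counts lower were 21 for plasma cell identity, 11 for immunoglobulin constant genes, 30 for interferon response, 9 for epithelial markers, 10 for cancer-testis antigens, 9 for class I presentation, 19 for chemokines and 12 for unfolded protein response, and the counts higher were 8 for myeloid markers and 10 for G1/S genes. With genes without reads at their bound, the median of the immunoglobulin list was -10.4 in place of -12.9, and that of the cancer-testis list -5.3 in place of -7.7.

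RY and KO also differed in plasma cell and myeloid genes. Of 11 myeloid markers 8 were higher in RY and 0 lower, with AIF1 370-fold and ITGAM 183-fold above KO. MPO was higher too, with a log2 fold change of 9.12 that rested on the KO libraries, being 8.11 without KO replicate 1 and 13.4 without KO replicate 2. Of 27 plasma cell genes 21 were lower and 2 higher, and of 12 immunoglobulin constant genes 11 were lower and 1 higher. Of 52 G2/M genes 12 were higher, among them MKI67 (1414 ± 91.1 against 242 ± 54.6 CPM), and 3 lower, and of 43 G1/S genes 10 were higher and 1 lower. Camera called neither cell cycle list (adjusted p = 0.149 and 0.0803). Over all 18281 genes tested 4420 were higher in RY than in KO, no smaller a share than in either cell cycle list. B cell genes split, with 14 of 28 higher and 9 lower, and interferon genes split too, with 11 of 46 higher, such as IFITM2 (195 ± 2.68 against 1.58 ± 0.360 CPM), and 19 lower. Neither of these lists was called, with adjusted p = 0.439 and 0.565 by camera.

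In all, 9149 genes differed between RY and KO, 4420 higher and 4729 lower in RY. By fitted log2 fold change, genes with 0 reads in KO led the increases. CLEC2A was at least 1038-fold higher in RY, CAVIN2 at least 666-fold, OTOF at least 568-fold and CDK6-AS1, an antisense RNA, at least 562-fold. That order depends on the prior count, and CD69, with reads in KO (0.015 CPM, against 74.4 in RY), exceeded these bounds. CD8B (at least 24430-fold), DSG2 (at least 9908-fold), IGHG4 (at least 7316-fold) and TEAD1 (at least 6692-fold) led the decreases by the same ranking. These too are lower bounds, so their order among all genes is not fixed. By the criterion of 10 against 0.1 CPM, 405 genes of KO were off in RY and 170 genes of RY were off in KO, while 9 genes of WT were off in KO and 1 gene of KO was off in WT. Camera called 6 lists. Immunoglobulin constant genes (1.36e-12, and adjusted p = 0.469 with an estimated correlation), plasma cell identity (1.36e-12, and adjusted p = 0.538 with an estimated correlation), epithelial markers (0.000177, and adjusted p = 0.586 with an estimated correlation), cancer-testis antigens (0.0119, and adjusted p = 0.538 with an estimated correlation) and chemokines (0.0172, and adjusted p = 0.586 with an estimated correlation) were lower in RY, and myeloid markers (0.00846, and adjusted p = 0.586 with an estimated correlation) were higher. Adjusted over the list alone, 11, 21, 9, 8 and 17 members of the lower lists were lower, and 8 myeloid markers higher.

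Genes called in both KO and RY against WT went the same way for 693 and opposite ways for 947. By fitted log2 fold change, CDH4, SALL1, MME and GALNTL6 had the largest decreases shared by KO and RY. Each was at most 0.015 CPM in both edited lines and 3.91 to 96.9 CPM in WT. For genes without reads this ranking depends on the prior count. ALDH1A1 rose in both, to 10.7 CPM in KO and 0.733 CPM in RY; TRIM2 and DANT2 also rose in both but stayed under 1 CPM. Without KO replicate 1 the KO calls of TRIM2 and DANT2 were lost (adjusted p = 0.0523 and 0.0573, the highest over the alternatives planned for named genes, with 0.00222 and 0.00249 the lowest). Without WT replicate 1 their KO log2 fold changes were 3.70 and 3.75, and without WT replicate 2 they were 6.75 and 6.80. Of the former, 173 were higher in both and 520 lower in both. Of the latter, 638 were lower in KO and higher in RY. Independent lists of these sizes would share 160.6 higher and 334.8 lower genes, so the 173 shared higher genes were near that number. Unchanged groups simulated against the same WT libraries shared 0. With all groups drawn from a common mean, few genes could be called, so that 0 was close to fixed in advance. It does not show how far the shared WT libraries raise the overlap of changed groups. Across genes, the log2 fold changes of KO and RY against WT correlated at -0.11 (Spearman -0.14), where 20 simulations of unchanged groups gave 0.54 ± 0.011. The covariance was -0.59 against a simulated 0.065, a difference of -0.65. With 2 WT libraries the controls could not be split, so part of any overlap may come from the shared libraries. The correlation was 0.0098 without WT replicate 2, 0.11 with no filter on low counts and 0.076 without genes that RY-kind RNA could supply.

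The authors' deposited table of KO against WT listed 2336 genes, 757 higher and 1579 lower, of which 1947 were also called here, all 1947 with the same sign. It gave HDAC6 a log2 fold change of -2.07. The authors' deposited table of RY against WT listed 9877 genes, 4590 higher and 5287 lower, of which 8909 were called here, all with the same sign, and it did not list HDAC6.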

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

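The tests of HDAC6, of single genes between RY and KO and of the gene lists were planned, while the count of opposite calls, the tests of explanations and the genes named beside the shares, runs and raw reads were chosen after the results they bear on had been seen. A difference between the edited lines singled out 3 results. HDAC6 and the myeloid markers came from a test of RY against KO itself, and the opposite calls from a count. HDAC6 stood 2.63 log2 units higher in RY than in KO (adjusted p = 2.89e-06), lower than WT in KO and not in RY. The lines moved 947 genes in opposite directions against WT, and 638 of them were lower in KO and higher in RY. Opposite 2-fold calls against the same WT make a difference between RY and KO nearly certain, so its call for all 947 adds no support. No expected number was computed for opposite calls. The myeloid markers had a median log2 fold change of 4.95 between RY and KO (4.28 with genes without reads at their bound), with 8 of 11 members higher and 0 lower.

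The libraries labelled RY lacked abundant transcripts that WT and KO share, such as ITGB7 (57 raw reads in RY, 519247 in WT), and expressed genes that are low or absent in KO. Depth or normalization is excluded as the whole source by these raw reads, which no normalization entered. Each library labelled RY held at least 31368968 reads, against at most 42813888 in a WT library. The ratio of RY to WT in raw reads over library totals had a median of 0.16 on the log2 scale over the 18281 genes tested. Dividing by totals removes a factor shared by all genes, so this median by itself could not test depth. Genes expressed in a line and at under 1% of that level in another lay in 13 runs of at least 3 neighbours, against a mean of 2.28 and a maximum of 7 in 1000 shuffles, so cells of another origin than RPMI 8226 behind the RY label are a candidate explanation. Shuffling does not keep the shared regulation of neighbours such as HOX genes, which may also form runs. Apart from the runs, immunoglobulin genes made up at most 0.00059% of reads in RY, against 1.59% to 2.05% in WT and KO. By the criterion of 10 against 0.1 CPM, 421 genes of WT were off in RY. Log2 CPM correlated at 0.682 to 0.753 between RY and the other libraries, against 0.946 to 0.958 between WT and KO. These gaps do not rest on the shuffles, but RNA levels do not exclude an effect of the edit. For 26 genes of the runs, KO held under 1% of the RY level, from 0 CPM for AGBL4 to 2.66 for CLEC2B. For these, an effect of the RY edit in RPMI 8226 cells cannot be told apart from cells of another origin. RNA does not show whether the KO genome still holds them, and DNA reads would be needed.

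Genes high in RY and nearly absent from KO were present in WT at a low level. Such RNA would supply at least 50% of the WT level for 450 of the 638 genes lower in KO and higher in RY. Of all 18281 genes tested, 1702 met that limit. The limit needs a level in RY far above WT, so a gene lower in KO that meets it is almost bound to be an opposite call. This overlap therefore adds no support. Index hopping at an equal rate among the 7 libraries is excluded as the whole source, since a share like that in WT would reach every gene, while of 7455 genes with at least 20 CPM in RY each KO library held 208 under 1% of the RY level. RNA or cells of the RY kind in both WT libraries may be the source: of the same 7455 genes, 5 were under 1% of the RY level in WT replicate 1 and 0 in WT replicate 2. The mean WT level of 7 marker genes ran from 3.81% of RY for CDKN2C to 7.75% for ITGAM. All 7 are among the 210 genes below, so they add no separate support. Over the 210 genes the quartiles were 3.08% and 5.44% of RY in WT replicate 1, and 5.92% and 8.57% in replicate 2. Single genes lay far outside, such as MUC19 (0.167 and 0.522 CPM in WT, 32.6 in RY) and UACA (11.4 and 14.7 CPM in WT, 27.1 in RY). Over the 210 genes under 1% of the RY level in KO, levels in WT ranked like those in RY (Spearman 0.806 and 0.874, with 0.393 and 0.662 for the KO libraries, where the genes were chosen to be low). An effect of the knockout on genes that WT cells express cannot be told apart from this for the 210 genes: their level was 1.75 times as high in WT replicate 2 as in replicate 1 (median, 205 of 210 higher), against 1.17 (quartiles 0.922 to 1.53) for 2141 other genes at such WT levels, but genes regulated together may also differ that way between cultures.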

How the results depend on the processing

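In this part the fits without genes that RY-kind RNA could supply, without X-linked genes and with crossed replicate numbers were chosen after seeing the data, and the rest before the data were examined. Under the alternatives planned for it, HDAC6 kept its direction and its side of the threshold in KO against WT and in RY against KO. In RY against WT its log2 fold change lost the adjusted p threshold with a replicate block (0.579, adjusted p = 0.0642), and ran from 0.353 without WT replicate 1 to 0.786 without WT replicate 2. The causes were not tested.

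KO against WT gave 3014 genes by the adjusted p alone, where no fold minimum applies. The other alternatives gave 1454, without suppliable genes, to 2190, with limma-voom, and leaving out libraries 1480 to 2327. The replicate block gave 1603 genes, and 2065 with the KO numbers crossed, so the numbers are not shown to pair samples. Fitting only the 2 groups compared gave 1462 genes, against 1991 in the shared fit, and an adjusted p of 0.0067 by edgeR for HDAC6. Where an arm was left with 1 library, that library is assumed to vary like the other groups.

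The correlation of the fold changes of KO and RY reversed with no filter on low counts (0.107) and without suppliable genes (0.0757), and ran from -0.121 to 0.00977 on leaving out a library, reversing without WT replicate 2. The causes were not tested. The number of lists called by camera with an estimated correlation was 0 in KO against WT, 0 in RY against WT and 0 in RY against KO, and fry called 7, 27 and 30. Leaving out a library gave 4 to 14 lists in KO against WT, 8 to 12 in RY against WT and 6 to 10 in RY against KO. Of 3178 values under 6 kinds of alternative, 3117 kept their direction and their side of the thresholds, 61 lost the call and 0 reversed. They cover the called genes named by the rule, HDAC6 excepted, and the named HDAC and sirtuin genes, called or not. Depth limits genes without reads to 0.0262 CPM in RY, 0.0393 in WT and 0.0435 in KO.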

Other observations

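Of the tests in this part, that of X-linked genes within 10 Mb of HDAC6 was written before its result was seen, and all others, with the boundaries on chromosome 1 and the X chromosome, were chosen after, as were the single genes named. Along chromosome 1, the 435 protein-coding genes below 70 Mb had a median log2 fold change of -0.36 in KO against WT, 78% of the WT level, with 391 of them below 0. The 574 genes above 70 Mb had a median of -0.0043, and 8502 genes of the other autosomes -0.00042. All 7 bins of 10 Mb in the first stretch had a median below -0.3, against 0 of 242 bins on the other autosomes. All 11 HOXA genes tested were higher in RY than in KO, with HOXA9 at 59.7 against 0.0900 CPM.

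The genes beside HDAC6 were lower in KO over a far longer stretch than the list covers. RNA of the RY kind in the WT libraries is excluded as the whole cause, since the listed genes had a median log2 ratio of RY to KO of 0.41 (0.412), and a share near 5.56% would need one of at least 3. A lower dosage of a stretch of the X chromosome in the KO line may be the cause: X-linked genes within 10 Mb of HDAC6 and off the list had a median log2 fold change of -0.422 over 55 genes, as low as in 0.324% of 8323 stretches of other chromosomes. A loss from the short-arm end to the HDAC6 target is a candidate explanation, since the best single step lay in the gap between SUV39H1 (start 48695554) and TIMM17B (start 48893447), which holds HDAC6. The midpoint of the gap is -0.00688 Mb from the start of HDAC6, but the step is placed no closer than the gap, with medians of -0.97 before it and -0.018 after it; effects of HDAC6 loss itself on this stretch were not tested.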
